A study of Homo sapiens with 10 samples.

How the data were processed

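Umbilical cord blood CD34+ cells, isolated and frozen before the experiment, were incubated for 2 h with 10 uM 16,16-dimethyl prostaglandin E2 (dmPGE2, a stable analog of prostaglandin E2) or with the DMSO vehicle, and total RNA was profiled on Affymetrix expression arrays, per the labels. The PicoPure kit was used for RNA isolation, and biotin-labelled cRNA was made from 100 ng of total RNA by the Message Amp II protocol with repeated amplification. The authors deposited RMA values made in Affymetrix Expression Console, which are background-corrected, quantile-normalized, summarised per probe set and on the log2 scale. The versions of both tools, and whether all 10 arrays were processed together, are not given in the sources used here. The log2 scale of the deposited values was checked on the file: they lay between 2.29 and 15.2, with array medians of 6.24 to 6.33. Background correction and probe set summarisation could not be redone from RMA values.

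The file held 54675 probe sets, of which 62 were Affymetrix controls. The platform annotation gave exactly 1 gene for 41097 probe sets, several genes for 1801 and no gene for 11777. Entrez identifiers matched 41043 probe sets to the gene reference and changed 0 symbols. Each of 19775 genes was represented by the probe set with the highest mean over all arrays. The 4944 genes whose mean lay below the 25th percentile of all genes, at 5.59 log2, were left out, which left 14831 genes for the tests.

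The 10 arrays formed 8 groups: dmPGE2 and vehicle at 4, 25 and 37 °C in StemSpan-SFEM (StemSpan), a serum-free medium, and at 37 °C in LMD/HSA, a solution of low molecular weight dextran 40 (8%) and human serum albumin (5%). The groups at 37 °C in StemSpan had 2 arrays each, numbered 1 and 2, and the other 6 groups had 1 array each. The labels do not say whether the numbered arrays came from separate cultures or donors, so limma's p values measure only the spread between arrays. The camera p values of gene lists, described below, set genes against genes and are no evidence from replicates, least of all where a group has 1 array. As for any array study of this size, the number of arrays limits the precision. The lists, tests, alternatives and rule for named genes were fixed before the data were examined, and alternatives chosen after seeing the data are named as such.

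Comparisons used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with 1 coefficient per group over all 10 arrays. Tests were two-sided, with Benjamini-Hochberg adjustment over the 14831 genes and a threshold of 0.05. The 4 replicated arrays gave 2 residual degrees of freedom, the prior had 3.04, and the median moderated SD was 0.349 log2. A group with 1 array was thus assumed to vary like the arrays at 37 °C in StemSpan. Standard errors (SE) come from this fit. The average response over all conditions was fitted as condition plus treatment. A response in one condition minus that in another was tested as an interaction. Because the lone arrays give no spread of their own, the number of genes whose groups were at least 2-fold apart (1 on the log2 scale) by their means, in the same direction in every difference of single arrays, is given as a description. By chance, 33.3% of genes keep 1 direction in every difference of 2 against 2 arrays, and 66.7% in 1 against 2.

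The test was tried on simulated data with the design and spread of these arrays, in which 200 of 14831 genes were changed. Where the spread held no difference shared by same-numbered arrays, it recovered 0% of genes changed 2-fold and 9% of genes changed 4-fold, and called 2 unchanged genes. Where same-numbered arrays shared a difference, it recovered 0% at either size and called 0 unchanged genes. The spread there came from a fit with the array number as a term, and the difference was shuffled across genes. Changes above 4-fold were not simulated. Estimated changes were accurate in either case, with a mean of 0.99 log2 for a 2-fold change.

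The 28 gene lists covered cAMP and MAP kinase feedback, immediate early, inflammatory, stress and metabolic responses, survival, cell cycle, stem cell genes and markers of other blood and stromal cells. Lists were tested with camera, which compares a list with all other genes, at the preset correlation between genes of 0.01 and with an estimated correlation, and with fry, which tests whether a list moves on balance in 1 direction. Their p values were adjusted over the 28 lists. The estimated correlation came only from the residuals of the replicated arrays, in which the difference between array numbers counts as spread. Members past the threshold were counted over all genes tested and adjusted over the list alone.

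Named genes followed a rule. In each comparison it took the genes past the threshold with the largest changes in the same direction in every difference of single arrays. Where fewer passed, it took up to 5 genes each way with the largest changes of at least 2-fold in the same direction in every such difference, given as values. It added up to 4 members with the largest changes from each list described, and CREM, NR4A2, PDE4B, PDE4D, CXCR4, PTGER2, PTGER4 and CD34 throughout. Of the 371 genes so named in the tables, 203 had several probe sets, and in 82 these differed in sign. One HLA class II gene that the rule selected is not named, because its probe sets read donor alleles.

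The signal of a gene chosen by its change was also measured in arrays that took no part in the choice. Genes at least 2-fold apart in 1 dmPGE2 and 1 vehicle array at 37 °C in StemSpan were chosen, and their median change in the direction of that choice was taken in the other arrays. RNA quality was read as the log2 difference between 3' and 5' control probe sets for GAPDH and ACTB. The alternatives tried were no filter on dim genes or one at the 50th percentile, eBayes without a trend, the mean of all probe sets of a gene or each probe set on its own, cyclic loess between arrays, leaving out each replicated array, the array number as a term and, for the chosen genes, choices at 1.5-fold and 3-fold. The closing section gives their effect.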

Results

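Expression of 14831 genes was compared in cord blood CD34+ cells, a population rich in hematopoietic stem and progenitor cells, on 10 arrays. Cells had been treated for 2 h with 10 uM dmPGE2 or vehicle. The question of the series was which temperature and which medium allow the drug to activate its pathways. In StemSpan there was 1 array per treatment at 4 °C and at 25 °C, and 2 per treatment at 37 °C. In LMD/HSA at 37 °C there was 1 array per treatment. Array medians ran from 6.24 to 6.33 and SDs from 2.28 to 2.41 on the log2 scale. Values for groups with 1 array have no replicate error of their own, and the SE beside them is the one limma borrows from the arrays at 37 °C in StemSpan. Where one of the levels behind a difference lies below 5.59 log2, the value under which genes were left untested by their mean, the size of the difference is not exact.

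The arrays at 37 °C in StemSpan differed by their number in both treatments. Between the vehicle arrays, 2181 genes were at least 2-fold apart, with 758 higher and 1423 lower in number 1. Between the dmPGE2 arrays, 2423 genes were, with 950 higher and 1473 lower in number 1. Heat shock genes, which encode chaperones, were higher in number 1 in 18 of 18 members in both treatments, by a list median of 2.36 in vehicle and 2.17 in dmPGE2. Examples in vehicle were BAG3, higher by 3.68, FKBP4 by 3.54, DNAJB1 by 3.29 and HSPB1 by 3.18. Monocyte markers were higher in number 1 in 8 of 8 members, by medians of 1.63 and 1.54, and megakaryocyte and platelet markers in 10 of 10, by 0.88 and 0.82. The 3' to 5' differences for GAPDH were 0.86 and 0.89 in number 1 and 0.09 and 0.52 in number 2, for dmPGE2 and vehicle. Responses at 37 °C are therefore given also within each number, as dmPGE2 minus vehicle of number 1 and of number 2.

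At 37 °C in StemSpan, the 5 genes furthest above vehicle with dmPGE2 were GEM, DUSP4, SV2C, CREM and NR4A2. GEM, a GTPase induced by cAMP, was higher by 6.03 ± 0.47 log2 (SE, n = 2 against 2), at 13.06 ± 0.02 with dmPGE2 and 7.03 ± 0.82 with vehicle (SD, n = 2). DUSP4, a MAP kinase phosphatase, was higher by 5.62 ± 0.81, at 12.16 ± 0.20 against 6.54 ± 1.66. SV2C, a synaptic vesicle protein, was higher by 4.95 ± 0.38. CREM, a transcription factor of the cAMP response, was higher by 4.29 ± 0.46, at 13.19 ± 0.13 against 8.90 ± 0.74, and NR4A2, an orphan nuclear receptor, by 4.21 ± 0.59, at 13.66 ± 0.24 against 9.45 ± 1.18. The cAMP phosphodiesterases PDE4B and PDE4D were higher by 3.52 ± 0.75 and 1.76 ± 0.62. CXCR4, the receptor that guides stem cells to the marrow, was higher by 2.49 ± 0.42, at 14.06 ± 0.09 against 11.58 ± 0.83. Of the prostaglandin E2 receptors, PTGER4 was higher by 1.79 ± 0.54, whereas PTGER2 differed by 0.03 ± 0.63 and lay in opposite directions within the numbers. CD34 differed by -0.20 ± 0.39. The largest negative differences were in SMAD6, an inhibitor of BMP signalling, at -2.50 ± 0.73, RGS19 at -1.99 ± 0.56, CMPK2 at -1.97 ± 0.34, MYCN at -1.95 ± 0.49 and GIMAP7 at -1.88 ± 0.70.

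Within number 1 and number 2, the changes were 5.46 and 6.60 for GEM, 4.59 and 6.65 for DUSP4, 4.59 and 5.30 for SV2C, 3.67 and 4.90 for CREM, and 3.55 and 4.88 for NR4A2. They were 1.84 and 3.14 for CXCR4, 1.10 and 2.47 for PTGER4, 0.90 and -0.85 for PTGER2, and 0.64 and 2.89 for PDE4D. DUSP4 read 5.37 in vehicle number 2, below the filter value, so 6.65 and the mean are not exact for it. The other probe sets of CREM, NR4A2, DUSP4 and CXCR4 gave changes of the same sign. Among the lower genes, the probe sets of SMAD6 ran from -2.50 to -0.23 and those of MYCN from -1.95 to 0.063, and RGS19, CMPK2 and GIMAP7 had 1 probe set each. Number 1 had 503 genes at least 2-fold apart, 361 higher and 142 lower with dmPGE2, and number 2 had 808, 436 higher and 372 lower. In both, 287 genes were at least 2-fold apart in the same direction, 215 higher and 72 lower. With the same direction in every difference between the 2 dmPGE2 and 2 vehicle arrays, 288 genes had a mean at least 2-fold higher and 137 at least 2-fold lower. Of these 425, 67.8% were higher, and of the 433 genes that met the same criterion after cyclic loess between arrays, 79.0%. At an adjusted p under 0.05 limma found 0 genes, with a smallest adjusted p of 0.302, for GEM and SV2C, and 470 genes at an unadjusted p under 0.05. With the array number as a term 2388 genes passed, 1005 higher and 1383 lower, but the labels do not say what a number marks. Without that term the difference between numbers counts as spread. The fit then recovered 0% of genes changed 2-fold or 4-fold in simulated data with such a difference. Its count of 0 thus cannot tell a response of that size from none, and larger changes were not simulated. With 1 array left out limma found 55 genes without dmPGE2 number 1, 46 without dmPGE2 number 2, 39 without vehicle number 1 and 14 without vehicle number 2.

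**Figure D1:**
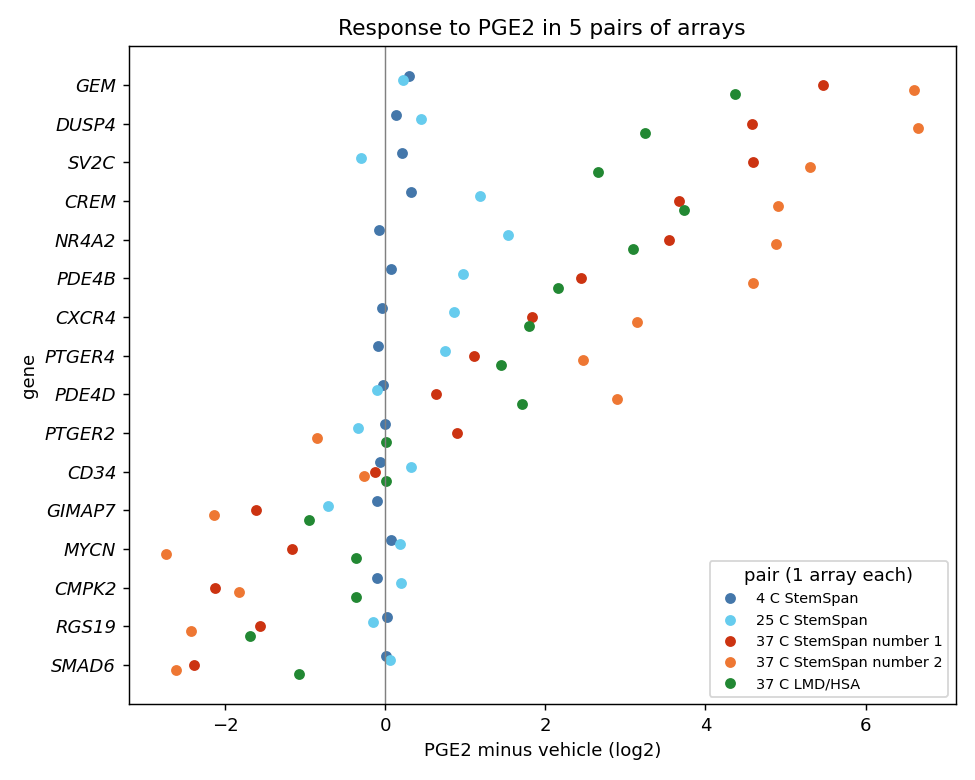
Horizontal position gives dmPGE2 minus vehicle on the log2 scale, and each line of points is 1 named gene in the 5 pairs of arrays, 1 point per pair. GEM stood at 5.46 and 6.60 in the pairs at 37 °C in StemSpan, 4.37 in LMD/HSA, 0.22 at 25 °C and 0.30 at 4 °C.

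In the gene lists at 37 °C in StemSpan, 9 of 28 rose relative to other genes by camera at the preset correlation. With an estimated correlation or by fry, 0 did. The estimated correlation rests on the few residuals of the replicated arrays. Calls lost with it, here and below, are therefore no evidence that a list did not move. The cAMP feedback genes, induced by cAMP and acting on its signal, had 9 of 20 members at least 2-fold higher, 0 lower, and a median of 0.97 (adjusted p = 4.37e-21 by camera and adjusted p = 0.324 with an estimated correlation). AKAP12, an anchor of protein kinase A, was higher by 4.20 ± 0.47 and the kinase SIK1 by 3.68 ± 0.36, with another probe set at -0.12 for AKAP12 and 0.079 for SIK1. Adjusted over the list alone, 8 members rose, and 0 over all genes tested. Immediate early transcription factors had 11 of 29 at least 2-fold higher, a median of 0.75 and 8 members that rose adjusted over the list alone (adjusted p = 3.46e-19, and adjusted p = 0.324 with an estimated correlation). Members were NR4A3 at 3.82 ± 0.58 and FOSL2 at 3.08 ± 0.41, and the list, named for its majority, also holds early genes that are no transcription factors, such as the kinase SGK1 at 3.78 ± 0.54. The list of MAP kinase phosphatases and feedback genes had 4 of 14 at least 2-fold higher and 1 lower, with a median of 0.60 and 3 that rose adjusted over the list alone (adjusted p = 1.46e-06, and adjusted p = 0.324 with an estimated correlation). DUSP2 was higher by 2.54 ± 0.38 and SPRY1 by 2.27 ± 0.46.

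Hypoxia and glycolysis genes had 5 of 21 members at least 2-fold higher and a median of 0.41, with 0 called adjusted over the list alone (adjusted p = 3.5e-06, and adjusted p = 0.324 with an estimated correlation). Examples were ANKRD37 at 2.02 ± 0.88, the glucose transporter SLC2A3 at 1.99 ± 0.78 and VEGFA at 1.83 ± 0.66. Glucocorticoid-responsive genes had a median of 0.59 over 10 members, of which 1 rose adjusted over the list alone (adjusted p = 0.000103, and adjusted p = 0.332 with an estimated correlation). NF-kappaB and inflammatory genes had 6 of 19 at least 2-fold higher, a median of 0.29 and 1 that rose adjusted over the list alone (adjusted p = 0.000169, and adjusted p = 0.324 with an estimated correlation). The chemokines CXCL2, CXCL3 and CXCL8 were higher by 3.82 ± 0.52, 2.12 ± 0.59 and 2.04 ± 0.75. Other members of the list were lower, with NFKBIE at -0.75, TNF at -0.62 and the chemokine CCL4 at -0.36. Prostaglandin receptors and metabolism genes had a median of 0.17 over 14 members, with 1 that rose adjusted over the list alone (adjusted p = 0.00656, and adjusted p = 0.366 with an estimated correlation), and PTGS2, which encodes an enzyme of prostaglandin synthesis, was higher by 2.18 ± 0.33. This call was lost without dmPGE2 number 1 (adjusted p = 0.0737) and without vehicle number 2 (adjusted p = 0.0923). Sterol biosynthesis genes had a median of 0.04 over 15 members, with 3 at least 2-fold higher and 2 that rose adjusted over the list alone (adjusted p = 0.00822, and adjusted p = 0.332 with an estimated correlation). They included SC5D at 2.39 ± 0.88 and STARD4 at 1.89 ± 0.42.

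Anti-apoptotic genes differed in sign by measure, with a median of -0.04, a mean of 0.23 and a test in the upward direction over 12 members (adjusted p = 0.049, and adjusted p = 0.366 with an estimated correlation). BCL2A1 was higher by 2.26 ± 0.29 and BIRC2 by 1.26 ± 0.35, while the 7 probe sets of XIAP ran from -0.71 for the one used to 0.82, with 2 of them negative. Apart from the correlation, the call held in 1 of 10 alternative settings, in which the adjusted p ran from 0.00377 to 0.246, and in 0 of the 4 that left out an array. Pro-apoptotic genes did not pass (adjusted p = 0.983), and held BCL2L11 at 2.28 ± 0.43 beside BMF at -1.53 ± 0.42. Homing and adhesion genes did not pass either (median -0.16, mean 0.10, adjusted p = 0.893), although S1PR1, a receptor that controls egress into blood, was higher by 1.79 ± 0.48. Stem and progenitor cell genes had a median of 0.13 (adjusted p = 0.0684), Wnt/beta-catenin targets a median of -0.09 and a mean of 0.04 (adjusted p = 0.876), and cell cycle genes a median of -0.11 (adjusted p = 0.893). Among cell cycle inhibitors CDKN1A was higher by 1.57 ± 0.46 and CDKN1C differed by -1.14 ± 0.38. Markers of monocytes and of megakaryocytes and platelets, which separated the array numbers, had medians of 0.05 and -0.10 between treatments, and heat shock genes 0.21 (adjusted p = 0.893, 0.277 and 0.199).

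**Figure D2:**
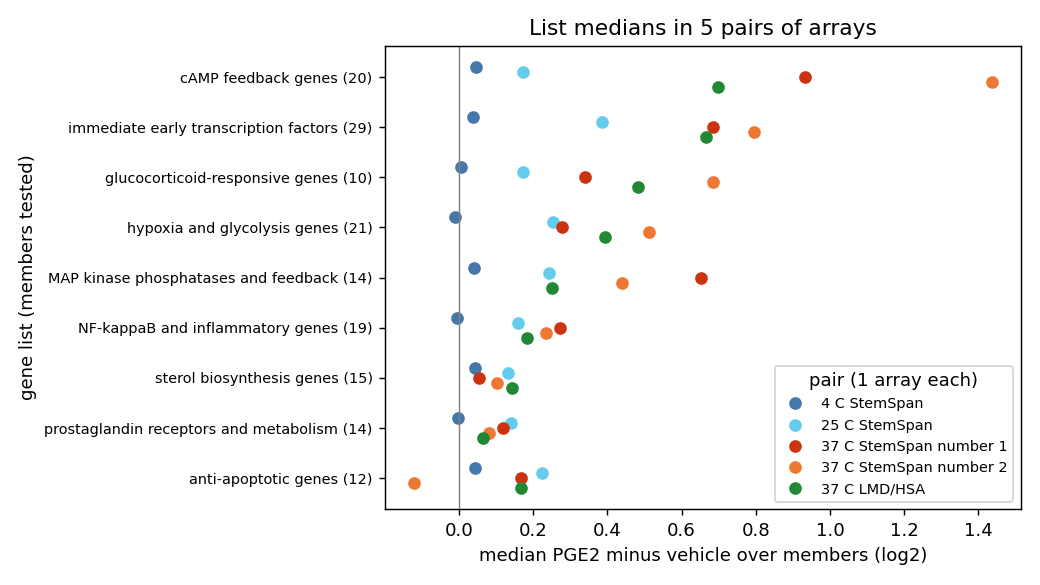
Horizontal position gives the median of dmPGE2 minus vehicle over the members of a list on the log2 scale, for the 9 lists that passed camera at the preset correlation at 37 °C in StemSpan, 1 point per pair of arrays. The cAMP feedback genes had medians of 0.93 and 1.44 at 37 °C in StemSpan, 0.70 in LMD/HSA, 0.17 at 25 °C and 0.04 at 4 °C.

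At 25 °C in StemSpan, 60 genes were at least 2-fold higher with dmPGE2 than with vehicle and 5 at least 2-fold lower. The largest differences were SLC32A1 at 2.87 ± 0.52, MCEMP1 at 2.48 ± 1.30, ID1, an inhibitor of differentiation, at 2.24 ± 0.71, the chemokine CXCL5 at 2.18 ± 1.52 and carbonic anhydrase CA2 at 2.10 ± 0.67. The 5 lower genes were SNAP23 at -1.20, ZNF823 at -1.10, MAP9 and GBP3 at -1.04 each and ZNF564 at -1.01. A level behind the differences of CXCL5, ZNF823 and GBP3 lay below the filter value. SGK1 was higher by 1.94 ± 0.77, SIK1 by 1.58 ± 0.51, NR4A2 by 1.54, DUSP2 by 1.47 ± 0.54, CREM by 1.19, PDE4B by 0.97 and CXCR4 by 0.86, whereas GEM differed by 0.22, DUSP4 by 0.44 and SV2C by -0.30. Immediate early transcription factors rose relative to other genes, with 26 of 29 members higher and a median of 0.39 (adjusted p = 2.31e-08 by camera). This call and the 6 that follow were lost at adjusted p = 0.576 with an estimated correlation. By camera at the preset correlation the test also passed for hypoxia and glycolysis genes (20 of 21 higher, median 0.25, adjusted p = 0.000842), anti-apoptotic genes (12 of 12, median 0.22, adjusted p = 0.00217), cAMP feedback genes (16 of 20, median 0.17, adjusted p = 0.0039), glucocorticoid-responsive genes (10 of 10, median 0.17, adjusted p = 0.0124), NF-kappaB and inflammatory genes (median 0.16, adjusted p = 0.0124) and NK cell markers (7 of 7, median 0.22, adjusted p = 0.0457). Adjusted over the list alone, 0 members of the 7 lists passed. The NK cell call held in 5 of 10 other settings, with an adjusted p of up to 0.61. Medians of this size were not particular to the lists that passed. Among the marker lists that did not, megakaryocyte and platelet markers had 0.20, stromal and endothelial 0.17, erythroid 0.15 and T cell 0.12. Granulocyte progenitor, monocyte and B cell markers had 0.03, 0.02 and 0.0036. For single genes limma found 0 at an adjusted p under 0.05 and 14 at an unadjusted p under 0.05.

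At 4 °C in StemSpan, 3 genes were at least 2-fold higher with dmPGE2 and 4 at least 2-fold lower. The higher ones were H2BC9 at 1.12, CTDSPL2 at 1.04 and IGFBP3 at 1.03. The lower ones were ADGRB3-DT at -1.20, CIP2A and H3C8 at -1.11 each and BCL11B at -1.06. BCL11B read 4.26 with dmPGE2 and 5.32 with vehicle, ADGRB3-DT 4.83 with dmPGE2 and IGFBP3 4.60 with vehicle, all below the filter value, so these sizes are not exact. Genes with large differences at 37 °C were close to the vehicle level, with GEM at 0.30 (levels of 4.94 and 4.64, below the filter value), CREM at 0.32, NR4A2 at -0.08, PDE4B at 0.07 and CXCR4 at -0.04. The median of the cAMP feedback genes was 0.04 and that of the immediate early transcription factors 0.04. By limma 0 genes passed, 2 had an unadjusted p under 0.05, and 0 of 28 lists passed by camera. The SD of the change over all genes was 0.173 at 4 °C, 0.268 at 25 °C, 0.443 and 0.554 in numbers 1 and 2 at 37 °C, and 0.374 in LMD/HSA.

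In LMD/HSA at 37 °C, 197 genes were at least 2-fold higher with dmPGE2 and 55 at least 2-fold lower. GEM was higher by 4.37 ± 0.66, MCEMP1 by 3.98 ± 1.30, INHBA, a subunit of activin, by 3.94 ± 2.09, PRMT9 by 3.82 ± 0.75 and CREM by 3.73 ± 0.65. DUSP4 was higher by 3.24, NR4A2 by 3.10 ± 0.84, SIK1 by 2.91 ± 0.51, SV2C by 2.66, PDE4B by 2.16, S1PR1 by 1.97, CXCR4 by 1.79 ± 0.60, PDE4D by 1.70 and PTGER4 by 1.44. The lower genes were led by MIR146A at -1.96, RGS19 and ELFN2 at -1.69 each, TAF2 at -1.63 and LACC1 at -1.62. Other probe sets gave 0.19 for MIR146A, 0.06 to 0.15 for ELFN2 and 0.08 for TAF2, and RGS19 and LACC1 had none. Of the 215 genes at least 2-fold higher in both numbers in StemSpan, 107 were also at least 2-fold higher in LMD/HSA, against 33 at 25 °C and 0 at 4 °C. Fewer of the 72 genes at least 2-fold lower in both numbers were shared, with 10 also at least 2-fold lower in LMD/HSA, 0 at 25 °C and 0 at 4 °C. Across genes, whose values are not independent replicates, the change in LMD/HSA had a Pearson r of 0.512 with number 1 and 0.543 with number 2. Those 2 had an r of 0.704 with each other, and 25 °C had 0.192 and 0.216 with them.

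The lists in LMD/HSA were led by cAMP feedback genes, with 9 of 20 members at least 2-fold higher, a median of 0.70 and 3 that rose adjusted over the list alone (adjusted p = 1.98e-13). With an estimated correlation this call and the 8 that follow were lost, at adjusted p = 0.603 for NK cell markers and adjusted p = 0.399 for the others. Immediate early transcription factors had 12 of 29 at least 2-fold higher and a median of 0.67 (adjusted p = 3.35e-14), and hypoxia and glycolysis genes 5 of 21 and 0.39 (adjusted p = 9.01e-07). MAP kinase phosphatases and feedback genes (median 0.25, adjusted p = 0.00152), glucocorticoid-responsive genes (0.48, adjusted p = 0.00589), cyclin-dependent kinase inhibitors (0.59, adjusted p = 0.00692), stem and progenitor cell genes (0.26, adjusted p = 0.0118), sterol biosynthesis genes (0.14, adjusted p = 0.0118) and NK cell markers (0.47, adjusted p = 0.0118) also rose relative to other genes. Of 10 other settings, the NK cell call held in 8 and the stem cell and kinase inhibitor calls in 9, with adjusted p values of up to 0.154, 0.0914 and 0.0619. By limma 0 single genes passed and 82 had an unadjusted p under 0.05. Without dmPGE2 number 1, dmPGE2 number 2 or vehicle number 1 at 37 °C in StemSpan 3 genes passed, and without vehicle number 2 there were 2. The 3' to 5' differences for GAPDH were 3.001 and 3.27 in the LMD/HSA arrays, against a highest value of 1.18 in StemSpan.

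The difference in response between temperatures was tested directly. Between 37 and 4 °C in StemSpan, the response differed by at least 2-fold in 491 genes, 312 positively and 179 negatively, with GEM at 5.73 ± 0.81, DUSP4 at 5.49 ± 1.40, SV2C at 4.74 ± 0.67, NR4A2 at 4.29 ± 1.03 and SGK1 at 4.04 ± 0.94. At the other end were SMAD6 at -2.50, PPP1R26 at -2.14, MYCN at -2.03 and RGS19 and FAM43A at -2.01 each. Between 37 and 25 °C, the response differed by at least 2-fold in 512 genes, 260 positively and 252 negatively, with GEM at 5.81 ± 0.81, SV2C at 5.25 ± 0.67, DUSP4 at 5.18 ± 1.40, AKAP12 at 4.16 ± 0.82 and the scaffold protein HOMER1 at 3.87 ± 0.55. FAM43A at -2.65 ± 1.01, SMAD6 at -2.57, SLC32A1 at -2.36, HES1, a Notch target, at -2.31 and CMPK2 at -2.18 lay at the other end. AKAP12 read 5.36 with dmPGE2 and 5.31 with vehicle at 25 °C, below the filter value, so the size of its difference is not exact. The same limit, given above, holds for DUSP4 and, against 4 °C, for GEM. The share of positive differences rested on the scaling, at 63.5% for 4 °C and 50.8% for 25 °C as deposited and 76.0% and 68.5% after cyclic loess, each of the genes then at least 2-fold apart.

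As lists, cAMP feedback genes responded more at 37 than at 4 °C by a median of 1.11 (adjusted p = 8.65e-22) and than at 25 °C by 0.97 (adjusted p = 9.02e-18) by camera at the preset correlation. Neither this call nor any below held with an estimated correlation, where the smallest adjusted p over the lists was 0.351 against 4 °C and 0.64 against 25 °C. Immediate early transcription factors responded more by 0.64 (adjusted p = 2.45e-17) and 0.44 (adjusted p = 8.96e-09), and MAP kinase phosphatases and feedback genes by 0.55 (adjusted p = 4.88e-06) and 0.37 (adjusted p = 0.000314). The smaller immediate early response at 25 °C went with a higher level in the vehicle array, which was also taken after 2 h. Relative to each gene's mean over the 10 arrays, that list had a median of 0.54 in vehicle and 0.79 with dmPGE2 at 25 °C. With dmPGE2 at 37 °C in StemSpan it had 0.15 and -0.14 in numbers 1 and 2. Against 4 °C the test also passed for hypoxia and glycolysis genes (median 0.35, adjusted p = 1.38e-05), NF-kappaB and inflammatory genes (0.20, adjusted p = 0.000496), glucocorticoid-responsive genes (0.41, adjusted p = 0.000496), prostaglandin receptors and metabolism genes (0.09, adjusted p = 0.0109) and sterol biosynthesis genes, whose median of -0.05 and mean of 0.37 differed in sign (adjusted p = 0.0241). The prostaglandin call was lost without dmPGE2 number 1 (adjusted p = 0.0793) and vehicle number 2 (adjusted p = 0.108), and the sterol call in 3 of 10 other settings, which were those without dmPGE2 number 2, without vehicle number 1 and without a filter, at an adjusted p of up to 0.0815. Adjusted over the list alone, 4 members passed against 4 °C and 2 against 25 °C. For single genes limma found 0 in either, with 103 and 75 at an unadjusted p under 0.05. Against 4 °C, 3 genes passed without dmPGE2 number 1, 3 without dmPGE2 number 2, 4 without vehicle number 1 and 0 without vehicle number 2, and against 25 °C these were 4, 3, 2 and 0.

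The response in LMD/HSA minus that in StemSpan at 37 °C was taken to compare the drug effect between media, from 1 array per treatment in LMD/HSA. It was at least 2-fold positive in 97 genes and at least 2-fold negative in 129. AKAP12 at -3.002 ± 0.82, ADTRP at -2.72 ± 0.67, LXN at -2.54, DUSP4 at -2.38 and the chemokine receptor-like CCRL2 at -2.38 ± 0.51 were lowest, and SNTG2-AS1 at 2.47, NKX2-3 at 2.20, PRMT9 at 2.14, NNT-AS1 at 1.89 and SLC32A1 at 1.73 highest. A level behind the values of ADTRP, DUSP4, SNTG2-AS1, NNT-AS1 and SLC32A1 lay below the filter value. Relative to other genes, 4 lists responded less in LMD/HSA: cAMP feedback genes by a median of -0.68 (adjusted p = 1.95e-07), NF-kappaB and inflammatory genes by -0.53 (adjusted p = 6.67e-05), immediate early transcription factors by -0.24 (adjusted p = 0.000278) and MAP kinase phosphatases and feedback genes by -0.46 (adjusted p = 0.00798). All 4 calls were lost at adjusted p = 0.86 with an estimated correlation. The immediate early call was also lost without dmPGE2 number 1 (adjusted p = 0.111) and without vehicle number 2 (adjusted p = 0.389), and so was the MAP kinase call (adjusted p = 0.176 and adjusted p = 0.228). By limma 0 genes passed and 33 had an unadjusted p under 0.05. The share of positive differences was 42.9% as deposited and 31.6% after cyclic loess, each of the genes then at least 2-fold apart. As list medians relative to each gene's mean, NF-kappaB genes stood higher with dmPGE2 in LMD/HSA (0.74) than in StemSpan (0.32 and 0.13). So did immediate early genes (0.79 against 0.15 and -0.14), and the smaller response of both lists went with a higher vehicle level in LMD/HSA. The cAMP feedback genes (0.52 against 0.84 and 1.76) and MAP kinase genes (0.11 against 0.25 and 0.47) stood lower.

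Vehicle arrays were compared to see what temperature and medium did without the drug, each lone array against both vehicle arrays at 37 °C in StemSpan. At 4 °C, 592 genes were at least 2-fold higher than at 37 °C and 1914 at least 2-fold lower, by the mean and in the same direction against both, and 1582 were at least 2-fold beyond both arrays. CYP1B1, an enzyme induced by the aryl hydrocarbon receptor, was lower at -5.91 ± 1.08, HSPA2 at -5.70 ± 1.11, CLDN11 at -5.64, HSPA6 at -5.24 ± 3.61 (-8.41 and -2.07 against numbers 1 and 2) and AHRR, the receptor's repressor, at -4.71 ± 0.64. At 4 °C the vehicle levels of CYP1B1, HSPA2 and CLDN11 were 5.01, 4.12 and 3.48, below the filter value of 5.59, and HSPA6 stood at 15.07 in number 1, near the highest value on the arrays, so the size and order of these differences are not exact. Higher were ZNF91 at 3.62, MATR3 at 3.50, ANKRD36 at 3.28, ZNF638 at 3.10 and HMGA2 at 3.06. ZNF91 and ANKRD36 read below the filter value in vehicle number 1, at 4.93 and 5.21. Other probe sets gave -5.81 to 0.27 for CYP1B1, 0.17 for CLDN11, -4.20 for HSPA6, 0.24 to 0.31 for ZNF91, -1.30 for ANKRD36, -0.89 to 2.45 for ZNF638 and -3.74 to 0.27 for HMGA2. The 18S control probe set read 13.82, against 11.89 and 11.91. Heat shock genes fell relative to other genes, with 16 of 18 members lower than in both arrays and a median of -1.77, which was -3.21 against number 1 and -0.79 against number 2 (adjusted p = 0.00381). This call and those of the 4 lists that follow were lost at adjusted p = 0.907 with an estimated correlation. Stem and progenitor cell genes rose by a median of 0.38 (0.71 and 0.29), with FLT3 at 2.57 ± 0.85, MLLT3 at 2.23 ± 0.59 and PROM1 at 2.13 ± 0.85 (adjusted p = 0.0146). The amino acid response genes fell by 0.44 (adjusted p = 0.0279), and granulocyte progenitor markers and immediate early transcription factors rose by 0.39 (0.07 and 0.78, adjusted p = 0.0313) and 0.41 (0.14 and 0.76, adjusted p = 0.0354). B cell markers had a larger median, 0.54 (0.27 and 0.62), with 7 of 10 higher than both arrays and 1 lower, and did not pass (adjusted p = 0.0643). Of 10 other settings, the immediate early call held in 4, with an adjusted p of up to 0.733, the granulocyte call in 6, with up to 0.363, and the amino acid call in 7, with up to 0.0938. The values of 0.733 and 0.363 came from leaving out vehicle number 2, and 0.0938 from leaving out vehicle number 1.

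At 25 °C, 1131 genes were at least 2-fold higher than in vehicle at 37 °C and 1683 at least 2-fold lower, and 1730 were at least 2-fold beyond both arrays. OSR2, at 4.47 and 4.68 in the 37 °C arrays and thus below the filter value of 5.59, was higher by 5.26 ± 0.26, a size that is not exact, the immediate early gene EGR4 by 4.89 ± 0.82, ZBTB24 by 3.46 ± 0.55 and the calcium-binding protein S100A8 by 3.37 ± 1.67 (1.89 and 4.86). AHRR at -4.94 ± 0.64, HSPA6 at -4.59 ± 3.61 (-7.77 and -1.42), LLPH at -4.21, SLC5A3 at -4.08 and SAMD4A at -4.07 were lowest. Other probe sets gave 0.48 to 3.67 for EGR4, -0.36 to 2.47 for ZBTB24, -0.38 for LLPH and -0.34 to 0.26 for SAMD4A. Immediate early transcription factors rose, with 16 of 29 members at least 2-fold higher, 10 that rose adjusted over the list alone and a median of 1.24, or 0.74 and 1.49 against numbers 1 and 2 (adjusted p = 2.57e-08). This call and the 2 that follow were lost at adjusted p = 0.864 with an estimated correlation. FOSB was higher by 3.33 ± 0.34, EGR1 by 3.04 ± 0.44 and CITED2 by 2.92 ± 0.70. Heat shock genes fell by a median of 1.49, with -2.63 against number 1 and -0.59 against number 2 (adjusted p = 0.000125). Monocyte markers rose by 1.51, or 0.93 and 1.88 (adjusted p = 0.0433), a call that was lost without vehicle number 2 (adjusted p = 0.0959) and with the filter at the 50th percentile (adjusted p = 0.342). Of other cell markers, B cell markers had a median of 0.48 (0.27 and 0.64), with 8 of 10 higher than both arrays and 1 lower, and granulocyte progenitor markers one of 0.31 (0.12 and 0.62), with 5 of 7 higher and 0 lower, and neither list passed. The GAPDH 3' to 5' difference was 1.18, against 0.89 and 0.52.

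In LMD/HSA, 861 genes were at least 2-fold higher than in vehicle in StemSpan at 37 °C and 1840 at least 2-fold lower, and 1566 were at least 2-fold beyond both arrays. COXFA4L3 was higher by 4.04 ± 1.07, ELFN2 by 3.49, WNT2B by 3.13 ± 0.32, EGR4 by 3.10 ± 0.82 and GADD45B, a stress-response gene, by 3.08 ± 0.72. The chaperone HSP90AB1 was lowest at -5.30 ± 0.39, followed by ZNF578 at -4.17, ZNF345 at -4.15, the translation factor EIF5A at -4.14 and DCAF7 at -4.11. Other probe sets gave -4.81 to -0.55 for HSP90AB1, 0.22 for ZNF345, -0.67 to -0.44 for EIF5A, -1.87 to 0.25 for DCAF7 and 0.16 to 0.31 for ELFN2. ZNF578 and ZNF345 read 4.27 and 4.37 in LMD/HSA and WNT2B 5.26 in vehicle number 2, below the filter value, so their differences are not exact. NF-kappaB and inflammatory genes rose, with 12 of 19 at least 2-fold higher and a median of 1.25, or 0.92 and 1.38 (adjusted p = 0.00118), among them CXCL1 at 2.30 ± 0.74 and NFKBIA at 1.90 ± 0.44. This call, the immediate early call and the heat shock call were lost at adjusted p = 0.989 with an estimated correlation. Monocyte markers had a median of 0.97 (0.32 and 1.73), with 6 of 8 higher than both arrays and 0 lower, and granulocyte progenitor markers 0.40 (0.15 and 0.64), with 6 of 7 higher and 0 lower, and neither list passed. Immediate early transcription factors rose by 0.91, or 0.79 and 1.08, with 14 of 29 at least 2-fold higher (adjusted p = 0.000761) and FOSB at 3.06 ± 0.34, while MYC was at -2.85 ± 0.76. Heat shock genes fell by a median of 1.63, or -2.55 and -0.37 (adjusted p = 0.000761), a call that was lost without vehicle number 1 (adjusted p = 0.177). GAPDH 3' to 5' differences, 3.27 here against 0.89 and 0.52, and the 18S control probe set, at 8.85 against 11.89 and 11.91, also separated the media.

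For single genes in these vehicle comparisons limma found 0 at an adjusted p under 0.05, with smallest adjusted p values of 0.176 at 4 °C, 0.0799 at 25 °C and 0.232 in LMD/HSA. At an unadjusted p under 0.05 there were 1653, 1839 and 1698. Leaving out vehicle number 1 gave 91, 17 and 48 genes, leaving out vehicle number 2 gave 172, 25 and 38, and leaving out dmPGE2 number 1 or 2, which alters only the estimate of spread, gave 428 or 423, 229 or 235 and 227 or 245. The lone arrays carry no number, so temperature and medium cannot be told apart from whatever the numbers mark.

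**Figure D3:**
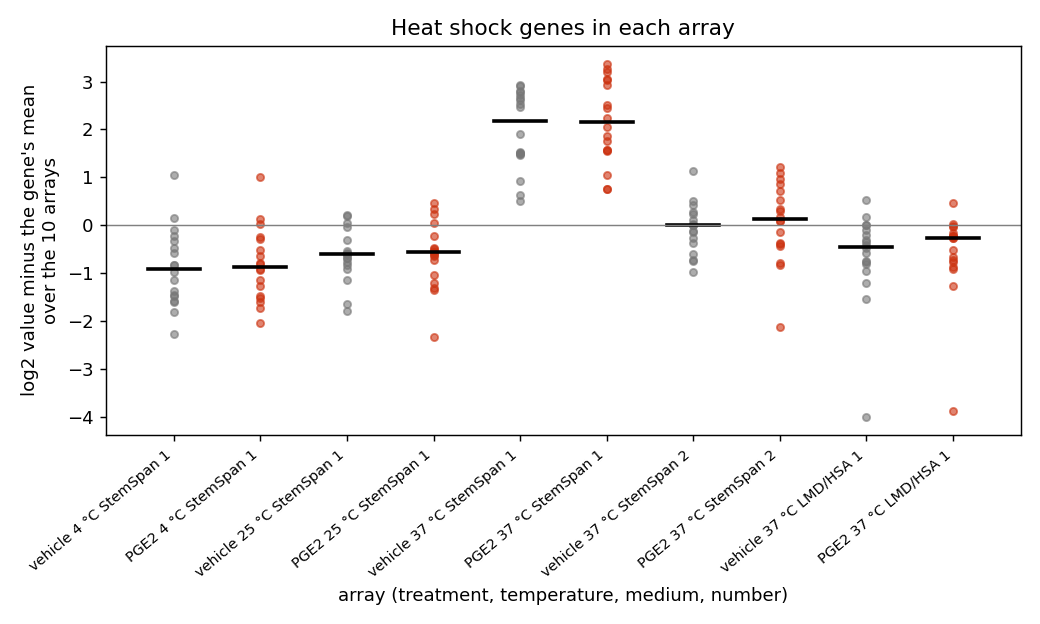
Each point is 1 of 18 heat shock genes in 1 array, as its log2 value minus the gene's mean over the 10 arrays, with dmPGE2 in red, vehicle in grey and a bar at the median. Both arrays numbered 1 at 37 °C in StemSpan lay above those numbered 2, by a list median of 2.36 in vehicle and 2.17 in dmPGE2.

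Over all conditions, the mean response of 5 dmPGE2 against 5 vehicle arrays was 3.39 ± 0.93 for GEM, 3.01 ± 0.91 for DUSP4, 2.76 ± 0.61 for CREM, 2.53 ± 0.93 for INHBA and 2.53 ± 0.68 for CXCL5. GIMAP7 and EFNA1 were lowest at -1.11 ± 0.41 and -1.02 ± 0.31. In all 5 pairs in the same direction, 61 genes had a mean at least 2-fold higher and 3 at least 2-fold lower, where chance keeps 1 direction in 6.25% of genes. By limma 0 genes passed, with a smallest adjusted p of 0.883, and 796 had an unadjusted p under 0.05.

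In arrays that took no part in choosing them, genes at least 2-fold apart in 1 dmPGE2 and 1 vehicle array at 37 °C in StemSpan had a median change of 0.13 in the remaining 37 °C arrays, with -0.72 to 1.13 over the 4 choices. The same genes had 0.34 in LMD/HSA (0.07 to 0.59), 0.09 at 25 °C (-0.01 to 0.17) and 0.0047 at 4 °C (-0.02 to 0.02). Choices across numbers took 2796 and 2991 genes and gave the negative values, since they also select the difference between numbers. With the choice limited to arrays of the same number, an alternative added after seeing the data, the 503 genes of number 1 had a median of 1.13 in number 2 and the 808 genes of number 2 had 0.79 in number 1. Choosing at 1.5-fold or 3-fold moved the mean over the 4 choices to 0.029 or 0.36 at 37 °C, 0.18 or 0.64 in LMD/HSA, and 0.049 or 0.17 at 25 °C. For same-number choices the mean was 0.96, against 0.55 in LMD/HSA, 0.15 at 25 °C and 0.0067 at 4 °C.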

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

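Tests of explanations were not run in this part. FAM43A was picked out because its response to dmPGE2 lay in opposite directions at the compared temperatures. At 25 °C in StemSpan it was 1.04 log2 higher with dmPGE2 in the only pair of arrays, and at 37 °C it was lower in both numbers, at -1.82 and -1.40, with a mean of -1.61. The criterion itself was not a test. The limma interaction, 37 minus 25 °C, was -2.65 ± 1.01 and did not pass (adjusted p = 1). Among the 425 genes that moved in the same direction in every difference at 37 °C in StemSpan with a mean of at least 2-fold, 1 such gene was found at 25 °C, 0 at 4 °C and 0 in LMD/HSA. No group had enough arrays for a check of single arrays far from the rest of their group.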

How the results depend on the processing

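Settings that take only the 37 °C StemSpan arrays of 1 number were chosen after seeing the data, and the other settings were planned. No gene passed limma's adjusted threshold without a filter on dim genes, with a filter at the 50th percentile, without a trend, with the mean of all probe sets, with each probe set on its own or after cyclic loess, in any of the 11 comparisons. These counts of 0 tell nothing of stability, since for 37 °C in StemSpan the reported fit recovered 0% of genes changed 2-fold and at most 9% of those changed 4-fold in simulated data. Counts of genes at least 2-fold apart were within 1.5 times the reported ones except as follows, and the cause was not tested unless given. The stricter filter left 3 genes at 4 °C, where fewer genes were tested. The mean of all probe sets gave 156 for LMD/HSA, 333 for 37 minus 25 °C, 143 for LMD/HSA minus StemSpan, 1693 for vehicle at 25 °C and 1738 for vehicle in LMD/HSA. Each probe set on its own, which gives a gene several chances, gave 657 for 37 °C in StemSpan, 140 for 25 °C, 15 for 4 °C, 436 for LMD/HSA, 788 for 37 minus 4 °C, 853 for 37 minus 25 °C, 477 for LMD/HSA minus StemSpan, 3913 for vehicle at 4 °C and 4233 for vehicle in LMD/HSA. Arrays numbered 1 alone gave 349 for LMD/HSA minus StemSpan. Arrays numbered 2 alone gave 808 for 37 °C in StemSpan, 939 for 37 minus 4 °C, 971 for 37 minus 25 °C, 573 for LMD/HSA minus StemSpan and 4155 for vehicle in LMD/HSA. The genes chosen at 3-fold had a held-out change of 0.64 in LMD/HSA and 0.36 at 37 °C, and those chosen at 1.5-fold 0.18 and 0.029, of which the first moved by more than the spread over choices. The 4944 genes below the filter value of 5.59 log2, a percentile and not a measured background, were tested only without the filter.

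With the array number as a replicate block, which pairs same-numbered arrays, limma passed 2388 genes at 37 °C in StemSpan, 8 at 25 °C, 182 in LMD/HSA, 280 for 37 minus 4 °C, 202 for 37 minus 25 °C, 22 for LMD/HSA minus StemSpan, and 4929, 5942 and 6894 for vehicle at 4 °C, at 25 °C and in LMD/HSA. The counts at 4 °C and over all conditions stayed at 0. Same-numbered arrays deviated together, with a Pearson r of 0.862 across 14831 genes between the number differences in dmPGE2 and vehicle, but the labels do not say what a number marks and there were 2 pairs only. The block leaves 1 residual degree of freedom, and in simulated data with a shared difference it recovered 100% of changed genes and called 17 unchanged ones. Those data took their spread from this same fit, which favours it. Without a shared difference it recovered 3% of genes changed 2-fold and 64% of those changed 4-fold, and called 38 unchanged ones. The counts for vehicle rest on lone arrays whose place among the numbers is unknown, so the difference between numbers stays in them while the spread leaves it out.

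Leaving out 1 array at 37 °C in StemSpan gave 14 to 55 genes past the threshold there (14 without vehicle number 2, 55 without dmPGE2 number 1), 2 to 3 in LMD/HSA, 0 to 4 for 37 minus 4 °C, 0 to 4 for 37 minus 25 °C, 91 to 428 for vehicle at 4 °C, 17 to 235 at 25 °C and 38 to 245 in LMD/HSA. Each of the 4 arrays moved these counts, except vehicle number 2 for the differences between temperatures. Counts of genes at least 2-fold apart, which then need fewer differences to share a direction, ran from 999 to 1319 for 37 °C in StemSpan, 1129 to 1397 for 37 minus 4 °C, 1095 to 1592 for 37 minus 25 °C, 723 to 1300 for LMD/HSA minus StemSpan and 2481 to 4155 for vehicle in LMD/HSA, where 4155 was without vehicle number 1. The remaining counts stayed at 0 or within 1.5 times.

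Of 51 calls of gene lists, 0 held with an estimated correlation, and the other settings made 50 to 74 calls. That correlation rests on the residuals of the replicated arrays alone, which hold the difference between array numbers. With it, the smallest adjusted p of any list in any comparison was 0.324. The loss of every call thus cannot tell a list that moved from one that did not, and leaves the preset correlation unchecked. In single lists and settings 465 calls held and 96 were lost, 51 of them with the estimated correlation. For named genes 1569 values kept their side of the threshold, 246 came to pass it with a replicate block or without an array, and 28 turned sign. With the mean of all probe sets these were CXCR4 at 4 °C (0.023), HMGA2 in vehicle at 4 °C (-0.12), PDE4D in vehicle at 25 °C (0.45) and CXCR4 in vehicle in LMD/HSA (-0.11). After cyclic loess they were PTGER2 at 4 °C (0.0013) and CD34 over all conditions (0.029). Without 1 array, CD34 ran from -0.49 to 0.10 at 37 °C in StemSpan, -0.43 to 0.16 for 37 minus 4 °C, -0.10 to 0.50 for LMD/HSA minus StemSpan, -0.59 to 0.0094 in vehicle in LMD/HSA and -0.091 to 0.092 over all conditions. PTGER2 ran from -0.85 to 0.90 at 37 °C in StemSpan, -0.84 to 0.91 for 37 minus 4 °C, -0.52 to 1.24 for 37 minus 25 °C, -0.89 to 0.87 for LMD/HSA minus StemSpan, -0.76 to 1.00 in vehicle at 4 °C, -1.40 to 0.36 in vehicle in LMD/HSA and -0.34 to 0.20 over all conditions. For LMD/HSA minus StemSpan, PDE4D ran from -0.82 to 0.71 and PTGER4 from -1.07 to 0.39. In vehicle, CREM ran from -0.98 to 0.069 at 4 °C and from -0.20 to 0.85 in LMD/HSA, and CXCR4 from -0.14 to 1.04 in LMD/HSA.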

Other observations

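The tests of the heat shock genes and of the unequal response at 25 °C were chosen only after the results were seen, and the counts of splits were planned. Beside the lists above, several genes of other programs differed with dmPGE2 at 37 °C in StemSpan without passing limma over all genes. Among interferon-stimulated genes, which as a list did not pass (median 0.02, mean -0.10, adjusted p = 0.893), IFIT3 was at -1.68 ± 0.49, with another probe set at -0.01, and IRF1 at -1.53 ± 0.40. Other members of that list were higher, with ISG15 at 1.02, MX2 at 0.75 and MX1 at 0.55. The erythroid transcription factor KLF1 was at -1.10 ± 0.26, while the erythroid list did not pass (median -0.03, adjusted p = 0.983). THBS1, a platelet and matrix protein, was higher by 3.61 ± 0.42, and the stem cell factor receptor KIT by 1.18 ± 0.59. In the amino acid response list SLC7A5 was higher by 1.51 ± 0.68 and TRIB3 was at -1.10 ± 0.37, with another probe set at -0.0057 (adjusted p = 0.346 for the list). Granulocyte, T, B and NK cell markers and stromal and endothelial markers had medians of -0.08, -0.04, -0.18, 0.0035 and 0.13, and none of these lists passed. Cold-inducible and unfolded protein response genes did not pass either, with medians of -0.01 and 0.11, and neither did cyclin-dependent kinase inhibitors, with a median of -0.16.

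Genes that were at least 2-fold higher in both numbers at 37 °C responded unequally at 25 °C. Of these 215 genes, 33 were at least 2-fold higher at 25 °C and 138 were under 0.5 log2, among them GEM at 0.22 and DUSP4 at 0.44, while SIK1 was at 1.58 and NR4A2 at 1.54. Around a factor of 0.198 for every gene the changes at 25 °C had an SD of 0.502, or 1.34 times the highest SD of 10000 random lists, but those lists were matched on mean level and not on response, and in LMD/HSA at 37 °C the same genes had 0.669 against 0.5004, also 1.34 times, so response by 1 factor with a wider spread of responding genes stays open. A vehicle level at 25 °C that already stood at the 37 °C dmPGE2 level was argued against for the 138 genes as a set, which had a median of 2.09 log2 left to rise. Choosing genes by their rise at 37 °C favours such a distance, and a median does not speak for each gene. Whether the drug signal itself may differ by gene at 25 °C cannot be told from 1 pair of arrays.

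Heat shock genes were high in both arrays numbered 1 at 37 °C in StemSpan. The drug as the cause was argued against by the vehicle arrays, which differed by a list median of 2.36, and by 2.41 after cyclic loess. Incubation at the labelled 37 °C alone was argued against by the arrays numbered 2, which lay 0.77 above the 4 °C arrays where those numbered 1 lay 3.22 above, and by LMD/HSA at 37 °C, which lay 0.42 above. Between the numbers RNA quality was not decided, since number 1 lay above number 2 in 3 of 4 comparisons of the 3' to 5' differences. These were 0.77 and 0.37 for GAPDH and 1.03 and -0.05 for ACTB, in dmPGE2 and vehicle. Larger differences than in number 1 (GAPDH 0.86 and 0.89, ACTB 4.73 and 4.49) were read at 25 °C and in LMD/HSA (1.09 to 3.27 and 4.94 to 5.25). Heat shock medians there, relative to each gene's mean, were -0.61 to -0.26, against 2.15 and 2.19 in number 1. These values argue against 3' to 5' differences alone as the cause, though those arrays also differed in temperature or medium. A different lot of cells, or a different handling of the cultures, could have set the numbers apart and stays untested.

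Other splits of the arrays were counted for the response over all conditions, where the real split gave 0 genes at an adjusted p under 0.05. All 100 of 100 splits gave at least as many, the highest of the others 65, but a real count of 0 fixes that outcome, so this count decides nothing about chance. At an unadjusted p under 0.05 the real split gave 796 genes, and 9 of the 24 splits within conditions gave at least as many, the highest of the others 2018. A split within conditions keeps the drug difference in every condition whose arrays it does not swap, so it can hold a response too. The count of such splits therefore neither excludes chance nor speaks for it. The arrays at 37 °C in StemSpan differed by number in 2181 genes in vehicle. Whether that difference lay behind the split with 2018 genes was not tested.

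Genes with more than 1 probe set were read also by the median of their other probe sets. At 37 °C in StemSpan it had the same sign in 92.2% of the genes at least 2-fold higher with dmPGE2 and was itself at least 2-fold apart in 45.4%, against 77.8% and 6.17% of the genes at least 2-fold lower. In LMD/HSA the shares were 88.5% and 31.0% of the higher genes with dmPGE2, but 71.0% and 0 of 31 of the lower ones. At 25 °C they were 88.9% and 22.2% of the higher genes, and of the lower genes only 2 had another probe set. For vehicle, the shares of the higher and then the lower genes were 79.7% and 24.7% against 74.5% and 26.9% at 4 °C, 79.0% and 13.6% against 76.5% and 29.7% at 25 °C, and 72.9% and 11.97% against 75.3% and 29.8% in LMD/HSA. The control probe set for the 5' part of 18S ribosomal RNA read 13.95 and 13.82 at 4 °C, 8.63 and 8.85 in LMD/HSA and between 10.20 and 11.91 in the other arrays. In LMD/HSA, the 215 genes at least 2-fold higher in both numbers in StemSpan changed by a factor of 0.618 of their 37 °C response, with an SD of 0.669 around it and a Pearson r of 0.664 across genes, against 0.305 at 25 °C.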
